A study of Mus musculus with 12 samples.

How the data were processed

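RNA was measured by sequencing in 12 mouse tumours. Per the labels, total RNA was extracted with Trizol and made into libraries by an Illumina protocol, and the submitters' processing notes name STAR, HTSeq, limma and the mm10 assembly without versions or roles. The authors deposited 1 matrix of read counts per gene with 24062 gene names, of which 3707 had 0 counts in every tumour. The values were whole numbers and were used as raw counts. All 12 columns matched 1 sample title each. In 27 gene names a spreadsheet had turned the name into a date. The 4 lines that shared a name were dropped, which removed at most 0.0172% of the counts of a tumour. No gene of the mitochondrial genome was in the matrix, so 54 of the 55 fixed gene lists could be tested.

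Total counts per tumour were 27258872 to 38163626, which sets a floor of 3 counts per library for a gene with 0 counts (0.093 CPM on average over the Smarca4L/L tumours). Such floors cover counting error only, since reads without molecular identifiers are not independent molecules. The ribosomal RNA gene Rn45s took 1.065 to 2.158% of the counts, Rpph1 0.386 to 1.724% and the 10 most abundant genes of each tumour 7.302 to 15.946%. Spearman correlations of log2 CPM between tumours of 1 genotype were 0.871 to 0.963 and between genotypes 0.845 to 0.958, and no 2 libraries held identical values. The first 3 principal components held 26.4, 16.7 and 14.4% of the variance. Gene positions were taken from the GENCODE M21 annotation of the mm10 assembly by gene symbol.

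Groups followed the genotype label, of which only the p53 and Smarca4 parts are written here. Items withheld for evaluation, and the values of 1 tumour of another genotype on its own, are not reported here. Replicate numbers only name tumours, in accession order. Differential expression was tested with edgeR 4.0.16 in R 4.3.3, with TMM factors (0.862 to 1.136), the filterByExpr filter and robust quasi-likelihood F tests. An additive fit of the 11 compared tumours had terms for the Smarca4 class and the p53 label, tested 16358 genes, and had a biological coefficient of variation of 0.5 and 7 residual degrees of freedom. A fit with 1 mean per genotype over all 12 tumours tested 17108 genes (coefficient 0.498, 5 residual degrees of freedom) and gave the direct comparisons and the difference of the Smarca4L/L effect with and without the p53 label. The genotypes with neither label and with p53 and Smarca4L/+ had 1 tumour each, which was assumed to vary like the others. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Fold changes are log2, printed with their standard error (SE). Levels in CPM are TMM-scaled counts-per-million values, as mean ± SD over tumours.

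Gene lists of pathways, cell types and technical signs were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and the preset correlation of 0.01 between genes, and adjusted over the 54 lists. The lists of replication-dependent histone, Y-linked and dissociation genes were the technical signs. Calls were checked with the correlation estimated for each list and with fry. Levels of Smarca4, Trp53 and Ppargc1a, and list scores, were compared by exact two-sided permutation tests. A list score is the mean log2 CPM of the members after subtracting each gene's mean over all 12 tumours. In addition to the lists reported with a direction, alveolar type 1, erythroid and mast cell markers, and lists for hypoxia, MYC targets, SWI/SNF subunits, immediate early genes of dissociation and regulators of mitochondrial biogenesis were tested. Their medians for Smarca4L/L against no Smarca4 label were -0.10, -0.93, -1.32, 0.28, 0.08, 0.07, 0.24 and -0.09 in that order, and none of these 8 lists passed camera in any of the 6 comparisons between groups.

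Named genes followed a rule fixed, like the groups, tests, lists and most alternatives, before the data were examined. Smarca4, Trp53 and Ppargc1a were always named. Each comparison of the additive fit was to name the 6 rising and 6 falling genes with the largest change among those past the threshold with an average log2 CPM of at least 1 and no overlap of CPM ranges, and the direct comparisons 3 and 3. Because no gene passed by edgeR, the 3 genes per direction with the smallest p and that average level were named instead, as not passing. For each called list the members with the smallest p that passed, or else the 1 with the smallest p, were named. The 4 p53 targets with the smallest p were named for the p53 label. Alb, Scgb1a1, Sftpc, and values of single tumours in Cr2, Ucp1, Krt6a and Cyp2f2, were chosen after their values were seen. Ribosomal protein, histone, Serpina1, Prl2c and MHC genes have near-identical copies, and reads shared between them can be lost or misplaced.

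The tests were tested on simulated data with the depth and dispersion of these tumours, in 3 of the designs. For Smarca4L/L against no Smarca4 label edgeR recovered 9, 64.2 and 84.8% of genes changed 2, 4 and 8-fold, with 4 false calls, and DESeq2 recovered 25.4, 89.6 and 97% with 50 false calls. With the p53 label edgeR recovered 16.4, 67.2 and 93.9% with 6 false calls and DESeq2 41.8, 88.1 and 97% with 68. For p53 with Smarca4L/L against p53 alone edgeR recovered 0, 44.8 and 68.2% with 5 false calls and DESeq2 7.5, 77.6 and 93.9% with 89. camera called a list shifted by 0.5 log2 units in each design (adjusted p = 3.28e-07, 1.85e-07 and 0.00269) and 0 of 20 unchanged lists. The simulated genes varied independently and the lists were random. The false calls of camera on lists of correlated genes were therefore not tested, although real lists were correlated (0.66 estimated for the cytosolic ribosome).

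Alternatives were DESeq2 1.42.0, limma-voom with and without sample weights, upper quartile and library size scaling, no filter and a stricter filter, dispersion without robust estimation, Y-linked and leukocyte scores as covariates, sex-linked genes left out, other sets of tumours and model terms, and each tumour left out in turn. Fits without the 2 libraries whose Trp53 level went against their label, and without these and SL/L 1 (the library labelled Smarca4L/L alone, replicate 1), were added after the levels were seen. The tumour of another genotype was in no test of the additive fit.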

Results

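Gene-level read counts were measured in 12 tumours from genetically engineered mice, and 11 of them are compared here by the p53 and Smarca4 parts of their genotype labels. These fell into 6 groups, with 1 tumour with neither label, 3 with p53 alone, 2 with Smarca4L/+ alone and 2 with Smarca4L/L alone. The remaining groups had p53 with Smarca4L/+ (1 tumour) and p53 with Smarca4L/L (2 tumours). The twelfth tumour was of another genotype and entered only values taken over all 12 tumours, such as the mean that list scores refer to, and the fit of the direct comparisons. Single tumours are named in short form, with N for neither label, P for p53, SL/+ and SL/L for the Smarca4 labels, and a replicate number. The labels did not give the tissue, sex or batch of a tumour, nor what the letter L stands for. Total counts per tumour ranged from 27258872 to 38163626, and 17122 to 18208 genes had at least 1 count. Nothing in the labels said that tumours of a group came from separate animals, so p-values measure only the spread between these samples. Sftpc, which encodes the surfactant protein C of alveolar type 2 cells, took 0.414 to 3.43% of the counts across the tumours.

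The levels of the engineered genes were examined first. Smarca4 encodes the ATPase subunit BRG1 of SWI/SNF chromatin remodelling complexes and lies on chromosome 9, from 21616169 to 21704230, in the mm10 assembly (ENSMUSG00000032187). Its level was 78.7 ± 27.8 CPM (TMM-scaled counts-per-million; SD, n = 4) in Smarca4L/L tumours, against 189 ± 26.7 CPM (SD, n = 4) in tumours with no Smarca4 label. Every Smarca4L/L tumour was below every tumour with no Smarca4 label, and an exact two-sided permutation test gave p = 0.0286, the smallest its 70 arrangements allow. In the 3 Smarca4L/+ tumours the level was 101 ± 16.9 CPM (SD, n = 3), again below all tumours with no Smarca4 label (exact permutation p = 0.0286). Smarca4L/L and Smarca4L/+ tumours did not separate by this test (exact permutation p = 0.229). Smarca4 transcripts were lower and still present in both classes, with 51.8 CPM as the lowest value. Leaving out any 1 of the 4 tumours with no Smarca4 label gave an exact p of 0.0571.

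Trp53, the tumour suppressor gene encoding p53 (chromosome 11, 69580359 to 69591873, ENSMUSG00000059552), was at 8.6 ± 5.48 CPM (SD, n = 6) with the p53 label and 21.4 ± 11.5 CPM (SD, n = 5) without it. This difference did not pass the exact permutation test (p = 0.104). A pair of libraries went against their label. The library labelled Smarca4L/L alone, replicate 2 (SL/L 2), held 3.38 CPM of Trp53, below the 19.5 CPM of the next lowest tumour with no p53 label. The library labelled p53 alone, replicate 2 (P 2), held 18.9 CPM, above the other 5 tumours with the p53 label. Ppargc1a, a coactivator of mitochondrial biogenesis (chromosome 5, 51454250 to 51567726, ENSMUSG00000029167), was at 22.2 ± 7.12 CPM (SD, n = 4) in Smarca4L/L tumours and 16.3 ± 3.9 CPM (SD, n = 4) in those with no Smarca4 label, which did not pass (exact permutation p = 0.229).

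**Figure D1:**
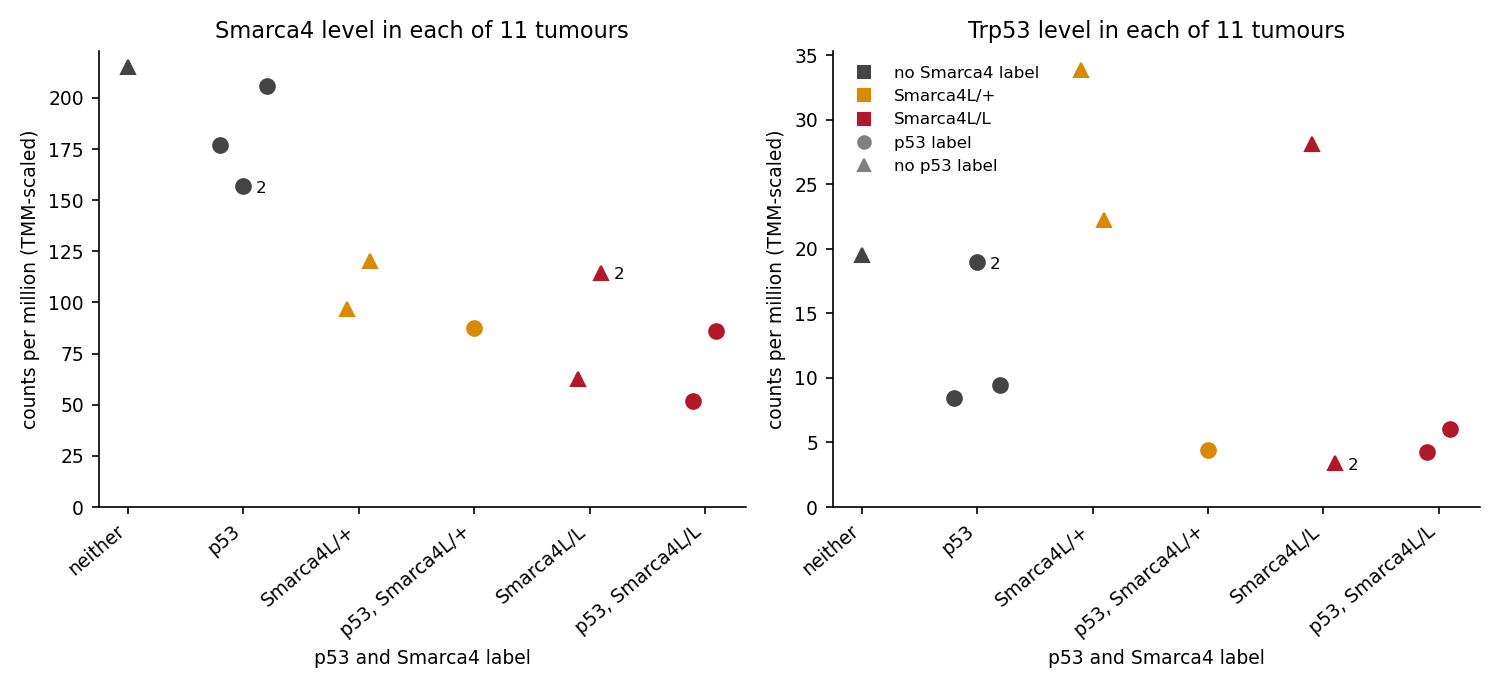
Levels of Smarca4 and Trp53 in CPM in each of the 11 compared tumours by p53 and Smarca4 label, with 1 point per tumour, colours for the Smarca4 label, circles for the p53 label, triangles for no p53 label, and "2" marking replicate 2 of Smarca4L/L alone and of p53 alone. Smarca4 lies between 51.8 and 114.4 CPM in Smarca4L/L tumours and between 156.7 and 214.9 CPM with no Smarca4 label, and the marked libraries hold 3.38 and 18.9 CPM of Trp53.

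The first comparison asked how tumours labelled Smarca4L/L differed from those with no Smarca4 label. Among the 11 tumours, adjusting for the p53 label, genes of protein synthesis and energy metabolism rose as groups (by camera, adjusted p = 0.893 with an estimated correlation for each list). All 53 cytosolic ribosomal protein genes were higher (median log2 fold change 0.42), among them Rps25, of the small subunit, at 249 ± 64.9 against 164 ± 21.8 CPM (SD, n = 4 each). The list score of SL/L 1 went the other way, at -0.406, the lowest of all tumours. Of the 76 nuclear genes of oxidative phosphorylation, 74 were higher (median 0.34), led by the complex III gene Uqcr10 at 48.9 ± 14.4 against 29.4 ± 3.64 CPM (SD, n = 4 each). The classes overlapped in this list score. SL/L 1 (-0.119) and PSL/L 1 (-0.055) lay below N 1 (-0.015), while SL/L 2 (0.299) and PSL/L 2 (0.397) lay above it. The 21 genes of cholesterol synthesis were all higher (median 0.71). The classes overlapped in this list score too, with PSL/L 1 (-0.113) below N 1 (-0.064) and P 3 (0.126). Insig1, which encodes a sterol-regulated brake on that pathway, was at 139 ± 29.8 against 62.0 ± 19.1 CPM (SD, n = 4 each), higher in 4 of 4 tumours than in any tumour with no Smarca4 label. Mitochondrial ribosome genes rose more weakly (median 0.20, 36 of 46 higher), with Mrpl3 at a log2 fold change of 0.49 ± 0.16 (SE). So did tricarboxylic acid cycle genes (median 0.21, 15 of 23 higher), a call lost without SL/L 2 (0.11). Idh3a, a subunit of isocitrate dehydrogenase, was at 65.7 ± 20.3 against 40.8 ± 13.2 CPM (SD, n = 4 each).

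Genes of cell division and of MHC class II antigen presentation fell in the same tumours (adjusted p = 0.893 with an estimated correlation for each list). MHC class I genes were not called by camera (median -0.06, 12 of 21 lower). The G2/M list fell with 37 of 45 genes lower (median -0.46), with a median of -0.27 without PSL/L 1, and DNA replication genes fell with 36 of 43 lower (median -0.38). In the G2/M score SL/L 1 (0.369) and PSL/L 2 (0.178) lay above N 1 (0.021), so the classes overlapped. Kif23, a motor protein of cytokinesis, had a log2 fold change of -1.01 ± 0.3 (SE), and Mcm5, a part of the replicative helicase, was at 12.4 ± 3.91 against 21.7 ± 5.86 CPM (SD, n = 4 each). The 11 genes of MHC class II presentation were all lower (median -0.98). Their master regulator Ciita was at 26.4 ± 8.61 against 92.7 ± 30.2 CPM (SD, n = 4 each), lower in 4 of 4 Smarca4L/L tumours than in any tumour with no Smarca4 label. T cell markers moved with these groups, with all 18 lower (median -3.03), a call lost without PSL/L 1 (-2.20) and P 2 (-0.21). Cd3g, a chain of the T cell receptor complex, was at 0.229 ± 0.171 against 4.73 ± 8.44 CPM (SD, n = 4 each). With a leukocyte score as covariate the MHC class II median was -0.79, and the T cell median was -0.61 with its call lost (adjusted p = 0.131). Dendritic cell markers fell too (median -1.10, 10 of 13 lower), a call lost without PSL/+ 1 (-0.96), P 2 (-0.24), PSL/L 2 (-1.04) and P 3 (-1.17). Their member with the smallest p, the calcium channel subunit gene Cacnb3, was at 21.5 ± 10.3 against 38.1 ± 21.9 CPM (SD, n = 4 each).

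Markers of several epithelial and vascular cell types also differed between these classes (adjusted p = 0.893 with an estimated correlation for each list). Basal and squamous markers rose (median 2.79, 11 of 14 higher), a call lost without SL/L 1 (0.87) and N 1 (2.58). Dsg3, a cadherin of squamous desmosomes, reached 5.67 CPM in SL/L 1 and was at 0.00791 ± 0.0158 CPM (SD, n = 4) with no Smarca4 label. Club cell markers rose (median 1.84, 11 of 11 higher), a call lost without SL/L 1 (1.48), N 1 (1.16) and PSL/L 2 (1.30). Their member Hp, which encodes haptoglobin, was at 1708 ± 862 against 436 ± 184 CPM (SD, n = 4 each), higher in 4 of 4 tumours. The club cell score did not separate the classes in this way. SL/L 2 had a score of -2.397, close to N 1 (-2.418), although it held 2153 CPM of Hp. Neuroendocrine markers rose (median 0.94, 10 of 14 higher), a call lost without SL/L 1 (0.68), N 1 (0.72) and PSL/L 1 (0.87), with Resp18, a neuroendocrine secretory protein gene, at a log2 fold change of 2.93 ± 1.08 (SE). Endothelial markers fell (median -0.40, 15 of 20 lower), a call lost without SL/L 1 (-0.31), PSL/L 2 (-0.30) and P 3 (-0.23), and Egfl7, secreted by endothelial cells, was at 24.3 ± 5.47 against 46.9 ± 15.0 CPM (SD, n = 4 each).

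No single gene passed this comparison by edgeR or limma-voom. edgeR found 0 of 16358 genes at FDR under 0.05, 1735 at an unadjusted p under 0.05 (889 higher, 846 lower; chance gives 818) and a smallest adjusted p of 0.102. DESeq2 called 343 (185 higher, 158 lower) and limma-voom 0. Il4i1, which encodes an L-amino acid oxidase, was closest, at 6.64 ± 6.52 against 41.2 ± 45.9 CPM (SD, n = 4 each; log2 fold change -3.12 ± 0.36 SE; edgeR adjusted p = 0.102). Others that did not pass were Noxo1, an organizer of NADPH oxidase 1 (-2.22 ± 0.34), and Ccnt2, a cyclin of the elongation factor P-TEFb (-0.93 ± 0.15; both edgeR adjusted p = 0.341). Rcn2, an endoplasmic reticulum calcium-binding protein gene, was at 55.8 ± 4.37 against 24.6 ± 3.93 CPM (SD, n = 4 each; edgeR adjusted p = 0.341). Gdpd1 (1.06 ± 0.19) and the scaffold gene Grasp (1.4 ± 0.25) had an edgeR adjusted p of 0.385. By camera with the preset correlation, 14 of 54 lists passed, from cytosolic ribosome (adjusted p = 1.48e-13), oxidative phosphorylation (8.9e-11), cholesterol synthesis (3.25e-08), G2/M (8.95e-07), MHC class II (2.27e-06) and DNA replication (4.19e-06) to dendritic cells (0.0313). None held with a correlation estimated for each list (adjusted p = 0.893 with an estimated correlation for each of the 14). Adjusted over the list alone, 1 cholesterol gene and 1 MHC class II gene passed, and 0 members of the other 12 lists.

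**Figure D2:**
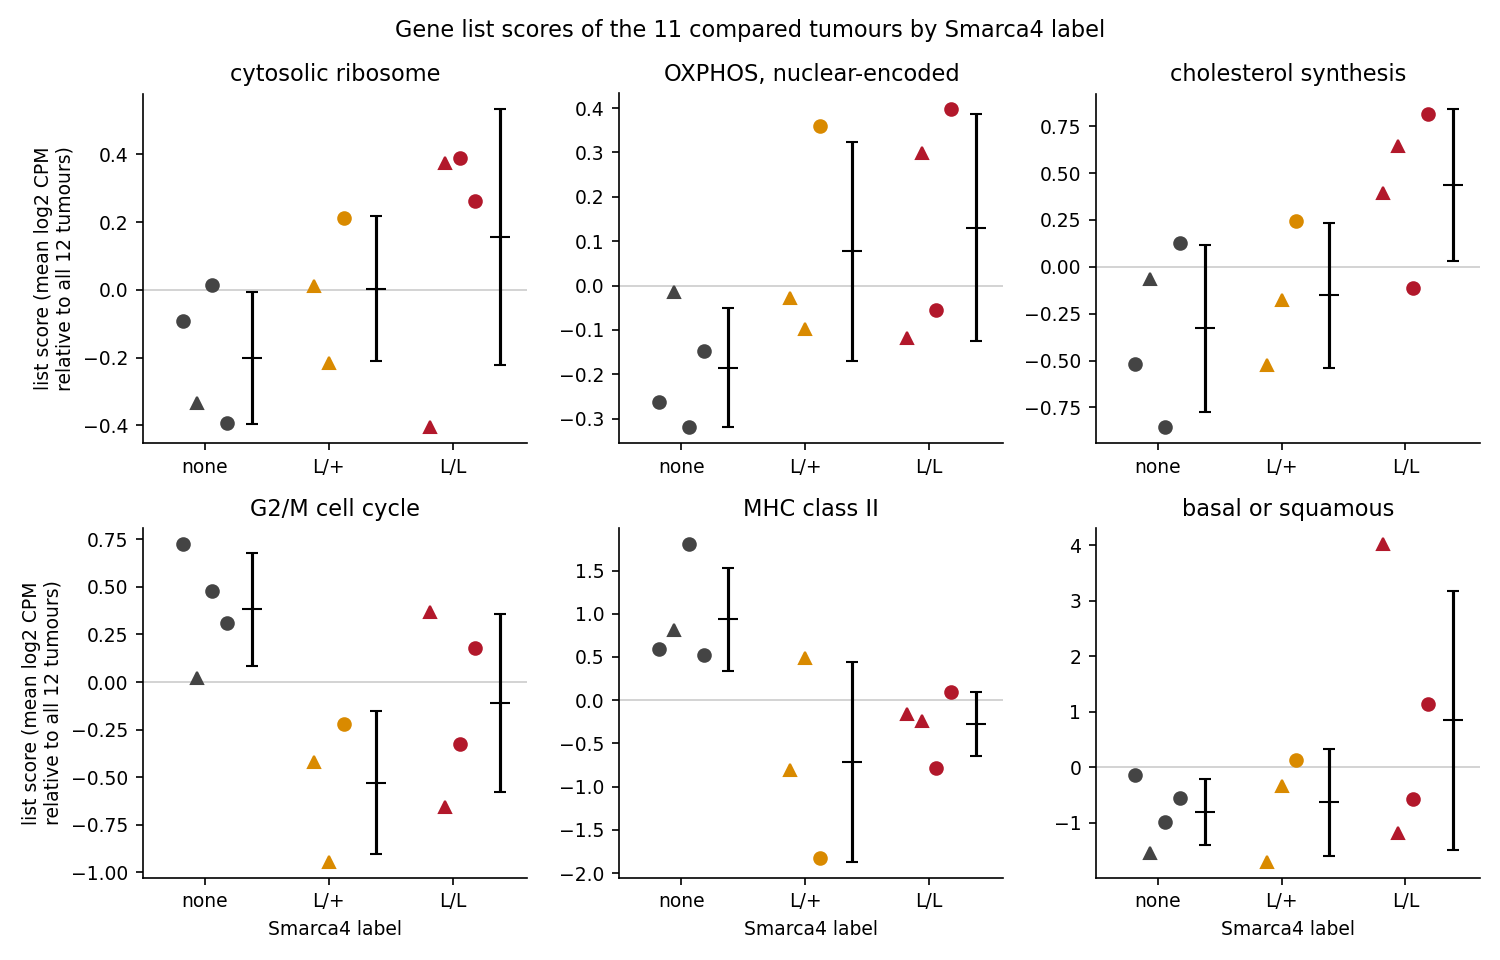
Mean log2 CPM of list members relative to the mean of all 12 tumours, for 6 gene lists, with 1 point per compared tumour by Smarca4 class, circles for the p53 label, triangles for no p53 label, and bars for the mean ± SD. The class means of cholesterol synthesis differ by 0.763 between Smarca4L/L and no Smarca4 label, while the basal or squamous panel is set apart by SL/L 1.

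The second comparison asked how Smarca4L/+ tumours differed from those with no Smarca4 label. Genes of cell division were lower as a group, with 43 of 45 G2/M genes lower (median -0.90) and 36 of 43 DNA replication genes lower (median -0.36), and both lists fell (adjusted p = 0.57 with an estimated correlation). For the other lists of antigen presentation and inflammation it was between 0.57 and 0.679. The proliferation marker Mki67 was at 34.6 ± 5.65 (SD, n = 3) against 99.01 ± 23.6 CPM (SD, n = 4), lower in 3 of 3 tumours than in any tumour with no Smarca4 label. Mcm5 had a log2 fold change of -1.13 ± 0.35 (SE). All 11 MHC class II genes were lower (median -1.47), with a median of -0.96 without PSL/+ 1, and Ciita was at 37.99 ± 29.9 (SD, n = 3) against 92.7 ± 30.2 CPM (SD, n = 4). Interferon response genes fell (median -0.59, 37 of 39 lower), with a median of -0.38 without P 2, and Stat2, a signal transducer of interferon receptors, was at 17.7 ± 3.78 (SD, n = 3) against 32.8 ± 6.85 CPM (SD, n = 4). MHC class I genes fell (median -0.46, 17 of 21 lower), a call lost without SL/+ 1 (-0.38), SL/L 2 (-0.42), PSL/+ 1 (-0.19), PSL/L 1 (-0.38) and P 2 (-0.33), with the peptide-trimming gene Erap1 at -0.52 ± 0.27 (SE). Inflammatory chemokine and cytokine genes fell (median -0.40, 21 of 31 lower), a call lost without SL/+ 1 (-0.21), P 1 (-0.43), SL/L 2 (-0.43) and PSL/L 1 (-0.34) and with a median of -0.25 without SL/L 1, -0.77 without SL/+ 2, -0.83 without PSL/+ 1 and -0.68 without N 1, with the alarmin gene Il33 at -1.74 ± 0.57 (SE).

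Metabolic groups rose in Smarca4L/+ tumours (adjusted p between 0.57 and 0.583 with an estimated correlation). All 53 cytosolic ribosome genes (median 0.31; Rps25 0.42 ± 0.21 SE) and 70 of 76 oxidative phosphorylation genes (median 0.30; Uqcr10 0.73 ± 0.24 SE) were higher, and for oxidative phosphorylation this was a call lost without PSL/+ 1 (0.06) and with a median of 0.49 without N 1. Mitochondrial ribosome genes rose (median 0.19, 35 of 46; Mrpl30 0.56 ± 0.2 SE), a call lost without PSL/+ 1 (0.09) and with a median of 0.11 without SL/+ 1 and 0.30 without N 1. Tricarboxylic acid cycle genes rose (median 0.25, 19 of 23; Sdhd, of complex II, 0.5 ± 0.16 SE). Fatty acid oxidation genes rose (median 0.22, 15 of 21; the electron transfer gene Etfa 0.42 ± 0.16 SE), a call lost without SL/+ 1 (0.10) and PSL/+ 1 (0.18) and with a median of 0.35 without N 1. Targets of the oxidative stress factor NRF2 rose (median 0.56, 28 of 32), a call lost without PSL/+ 1 (0.23). Gclm, of glutathione synthesis, was at 51.0 ± 19.9 (SD, n = 3) against 26.6 ± 2.57 CPM (SD, n = 4), higher in 3 of 3 tumours. Replication-dependent histone genes fell (median -0.41, 12 of 18; the linker histone gene Hist1h1d -1 ± 0.29 SE), a call lost without SL/+ 2 (-0.31) and N 1 (-0.14) and with a median of -0.92 without PSL/+ 1. This list was fixed as a technical sign, here and in the other comparisons.

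Programmes of some other epithelia rose (adjusted p = 0.257 with an estimated correlation for neuroendocrine markers and 0.57 to 0.635 for the other lists of this kind). Basal and squamous (median -0.94), club cell (-0.74) and ciliated cell markers (-0.51) had negative medians and were not called by camera. Hepatocyte genes rose (median 2.18, 11 of 16; the urea cycle gene Cps1 6.01 ± 1.43 SE), a call lost without PSL/+ 1 (-0.13). In that tumour Alb was at 216 CPM and Apob at 1680 CPM. Foregut and gastric programme genes rose (median 0.51, 15 of 19), a call lost without PSL/+ 1 (-0.04) and N 1 (-0.09) and with a median of 1.76 without P 1, 0.98 without SL/L 2, 0.99 without PSL/L 1 and 1 without PSL/L 2. Ctse, a gastric aspartic protease gene, was at 167 ± 105 (SD, n = 3) against 25.0 ± 19.9 CPM (SD, n = 4). Gastric and gut epithelium markers rose (median 0.29, 10 of 14), a call lost without PSL/+ 1 (-0.24) and N 1 (-0.39) and with a median of 0.54 without SL/L 1, 0.51 without SL/+ 2, 1.30 without P 1, 0.58 without SL/L 2, 0.62 without PSL/L 1, 0.19 without P 2 and 0.83 without PSL/L 2, with Cdh17, an intestinal cadherin gene, at 71.6 CPM in PSL/+ 1. Genes of a progression programme around the chromatin factor Hmga2 rose (median 0.60, 12 of 13), a call lost without PSL/+ 1 (0.16), and Hmga2 itself reached 34.4 CPM in that tumour. Neuroendocrine markers rose (median 1.45, 12 of 14; the ubiquitin hydrolase gene Uchl1 1.77 ± 0.61 SE), with a median of 0.79 without SL/+ 2, 0.86 without PSL/+ 1 and 0.76 without N 1. Alveolar type 2 markers fell (median -0.46, 13 of 16; Lamp3 -1.76 ± 0.79 SE), a call lost without SL/L 2 (-0.43), PSL/+ 1 (-0.13), N 1 (-0.35) and P 3 (-0.35) and with a median of -0.73 without SL/+ 2. Mesothelial markers fell (median -2.26, 9 of 10; Upk3b -4.27 ± 1.35 SE), a call lost without SL/+ 1 (-1.82) and N 1 (-1.66).

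Markers of blood, vascular and muscle cells were lower beside these groups (adjusted p between 0.583 and 0.635 with an estimated correlation). T cell (median -3.58, 18 of 18; Cd8b1 -4.65 ± 1.89 SE) and B or plasma cell markers (median -5.27, 12 of 12) fell. For T cells this was a call lost without PSL/+ 1 (-2.62) and with a median of -0.92 without P 2, and for B cells a call lost without PSL/+ 1 (-3.54) and with a median of -1.12 without P 2. Natural killer cell markers fell (median -2.82, 8 of 8; Klrd1 -3.21 ± 1.43 SE), a call lost without SL/L 2 (-2.42), PSL/+ 1 (-2.24), PSL/L 1 (-2.49) and P 2 (-1.13). Neutrophil markers fell (median -1.18, 13 of 16; Cxcr2 -0.8 ± 0.31 SE), a call lost without SL/+ 1 (-0.91) and P 2 (-0.65). Dendritic cell markers fell (median -0.98, 9 of 13; Clec9a -1.3 ± 0.59 SE), a call lost without SL/L 2 (-0.94), PSL/+ 1 (-0.38), P 2 (-0.27) and P 3 (-1.02) and with a median of -1.77 without SL/+ 2 and -1.52 without N 1. Endothelial markers fell (median -0.44, 16 of 20; Car4 -1.29 ± 0.83 SE), a call lost without SL/L 2 (-0.28), PSL/+ 1 (0.10) and P 3 (-0.40) and with a median of -0.68 without N 1. Cardiac muscle markers fell (median -1.83, 14 of 14; Ryr2 -3.18 ± 0.86 SE), a call lost without PSL/+ 1 (-0.76) and with a median of -0.99 without P 1. Skeletal muscle markers fell (median -1.05, 11 of 15; Ttn -2.48 ± 0.9 SE), a call lost without SL/+ 2 (-0.98), P 1 (-0.63), SL/L 2 (-0.50), PSL/+ 1 (-0.84) and PSL/L 1 (-0.94) and with a median of -1.61 without N 1. Adipocyte markers fell (median -1.38, 10 of 11; Adrb3 -2.74 ± 1.19 SE), a call lost without SL/L 2 (-0.72), PSL/+ 1 (-0.49), PSL/L 1 (-1.55) and P 2 (0.40) and with a median of -2.39 without SL/+ 1, -2.93 without SL/+ 2, -2.15 without N 1 and -2.33 without PSL/L 2.

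In this comparison edgeR found 0 genes at FDR under 0.05, 1125 at an unadjusted p under 0.05 (608 higher, 517 lower; chance gives 818), DESeq2 65 and limma-voom 0. The genes with the smallest p, none of which passed (edgeR adjusted p = 0.715), included Cdkn1c, a cyclin-dependent kinase inhibitor gene (2.76 ± 0.49 SE), Lrfn3 (1.94 ± 0.36) and the phosphodiesterase gene Smpdl3b (1.55 ± 0.3). Lower were the complement gene C6 (-2.68 ± 0.55), the corepressor gene Tle2 (-1.8 ± 0.39) and the transcription factor gene Foxp2 (-1.15 ± 0.22). Ppargc1a was at 26.5 ± 7.4 (SD, n = 3) against 16.3 ± 3.9 CPM (SD, n = 4; exact permutation p = 0.0857). By camera 29 of 54 lists passed, the G2/M list with adjusted p = 1.09e-15, and 12 of 54 without PSL/+ 1. None held with an estimated correlation. The adjusted p with an estimated correlation was 0.257 for neuroendocrine markers and between 0.57 and 0.679 for the other lists. Adjusted over the list alone, 1 hepatocyte gene and 0 members of the other called lists passed.

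The third comparison set Smarca4L/L against Smarca4L/+ tumours, where each called list had adjusted p = 0.995 with an estimated correlation. Cholesterol synthesis genes rose in Smarca4L/L tumours, with all 21 higher (median 0.63) and Insig1 at 139 ± 29.8 (SD, n = 4) against 61.2 ± 16.5 CPM (SD, n = 3), higher in 4 of 4. The list score of PSL/L 1 (-0.113) still lay below that of PSL/+ 1 (0.247). G2/M genes rose (median 0.41, 41 of 45), a call lost without SL/L 1 (0.07) and SL/+ 2 (0.26). Its member with the smallest p went the other way, since Kif23 was at -0.86 ± 0.32 (SE). Replication-dependent histone genes rose (median 0.53, 18 of 18; Hist1h3a 0.77 ± 0.35 SE), a call lost without SL/+ 2 (0.39) and with a median of 0.84 without PSL/+ 1. Interferon response genes rose (median 0.61, 35 of 39; the apoptosis factor gene Xaf1 0.88 ± 0.3 SE), a call lost without SL/L 1 (0.13) and SL/+ 1 (0.34) and with a median of 0.40 without PSL/L 2. NRF2 targets fell (median -0.31, 24 of 32), a call lost without PSL/+ 1 (0.00) and PSL/L 1 (-0.13) and with a median of -0.48 without SL/+ 2, and the catalase gene Cat was at 189 ± 23.8 (SD, n = 4) against 396 ± 67.8 CPM (SD, n = 3). Fatty acid oxidation genes fell (median -0.22, 15 of 21; Acadm -0.64 ± 0.28 SE), a call lost without SL/L 1 (-0.14), SL/+ 1 (-0.08), SL/L 2 (-0.18), PSL/+ 1 (-0.17), PSL/L 1 (-0.20) and P 2 (-0.22).

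Several cell type lists were called in this comparison (adjusted p = 0.995 with an estimated correlation for each). Club cell markers (median 2.18, 11 of 11 higher; Cyp2f2 3614 CPM in SL/L 1) rose, a call lost without SL/L 1 (-0.16) and PSL/+ 1 (2.06) and with a median of 4.06 without SL/+ 2. Ciliated cell markers rose (median 1.29, 18 of 20; the dynein gene Dynlrb2 1.46 ± 0.77 SE), a call lost without SL/L 1 (-0.82), SL/+ 1 (0.90), PSL/+ 1 (0.57) and PSL/L 2 (1.10) and with a median of 3.39 without SL/+ 2. Basal and squamous markers rose (median 3.02, 13 of 14; Krt6a 197 CPM in SL/L 1), a call lost without SL/L 1 (0.02), SL/+ 1 (1.56) and SL/+ 2 (2.59) and with a median of 4.67 without PSL/+ 1. Mesothelial markers rose (median 2.25, 8 of 10; Upk3b 3.89 ± 1.35 SE), a call lost without SL/+ 1 (1.83), SL/+ 2 (2.31), SL/L 2 (2.26) and PSL/L 2 (1.33). Extracellular matrix genes rose (median 0.36, 23 of 30; Col6a2, a collagen VI chain, 1.66 ± 0.39 SE), a call lost without SL/+ 1 (0.29), SL/L 2 (0.14), PSL/+ 1 (-0.08) and PSL/L 1 (0.21) and with a median of 0.64 without SL/L 1 and 0.80 without SL/+ 2. Fibroblast markers rose (median 0.40, 14 of 19; Inmt 1.63 ± 1.17 SE), a call lost without SL/+ 1 (0.30), SL/L 2 (0.13) and PSL/+ 1 (-0.19) and with a median of 1.09 without SL/+ 2. The fibroblast and matrix lists share genes, with 23 of the 30 matrix genes outside the fibroblast list. Hepatocyte genes fell (median -2.16, 12 of 16; the apolipoprotein gene Apob 7.01 ± 0.681 against 743 ± 838 CPM; SD, n = 4 and 3), a call lost without PSL/+ 1 (-0.42). Foregut and gastric programme genes fell (median -0.95, 13 of 19; Ctse -2.53 ± 0.75 SE), a call lost without PSL/+ 1 (-0.72) and with a median of -1.77 without SL/L 1, -0.28 without SL/+ 1 and -1.43 without SL/+ 2.

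For Smarca4L/L against Smarca4L/+, edgeR found 0 genes at FDR under 0.05, 785 at an unadjusted p under 0.05 (381 higher, 404 lower; chance gives 818), DESeq2 67 and limma-voom 0. Of the genes with an average log2 CPM of at least 1, those closest to passing (edgeR adjusted p = 0.963, the smallest of any gene being 0.46) were Add3, of the membrane skeleton, at 102 ± 32.0 (SD, n = 4) against 23.5 ± 11.7 CPM (SD, n = 3), Fxyd6 (2.61 ± 0.55 SE) and Grasp (1.31 ± 0.28 SE). Il4i1 was at -1.72 ± 0.36 (SE). Prl2c3, of a family with near-identical copies, had 0 counts in all 4 Smarca4L/L tumours and was at 0.681 CPM in SL/+ 1, 0.673 CPM in SL/+ 2 and 21.6 CPM in PSL/+ 1. The mean of 7.64 CPM, at least 82.1-fold above a floor of 3 counts per library, thus came mostly from 1 tumour. By camera 14 of 54 lists passed, cholesterol synthesis with adjusted p = 2.83e-06, and none held with an estimated correlation (adjusted p = 0.995 with an estimated correlation for each). Adjusted over the list alone, 1 cholesterol, 3 hepatocyte, 1 NRF2 and 1 matrix gene passed, and 0 members of the other 10 lists.

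The fourth comparison asked how tumours with the p53 label differed from the others of the 11, adjusting for the Smarca4 label. Genes of extracellular matrix and mesenchymal cells rose (adjusted p = 0.649 and 0.305 with an estimated correlation). For junction genes and fibroblasts that p was 0.649, and for macrophages 0.775. Of the 30 matrix and collagen genes 28 were higher (median 1.34), such as Col6a2 at 419 ± 284 (SD, n = 6) against 111 ± 65.0 CPM (SD, n = 5). Mesenchymal transition genes rose with 19 of 22 higher (median 1.19), and Twist1, a transcription factor of that transition, had a log2 fold change of 4.27 ± 0.8 (SE). Its level was low, at most 2.08 CPM (PSL/L 1), and the groups overlapped. P 2 (0.141 CPM) and P 3 (0.0307 CPM) lay below SL/+ 2 (0.161 CPM), a tumour with no p53 label. Epithelial junction and keratin genes fell with 24 of 26 lower (median -0.49), with a median of -0.74 without PSL/+ 1. Krt7, a keratin of simple epithelia, was at 333 ± 94.2 (SD, n = 6) against 989 ± 194 CPM (SD, n = 5), lower in 6 of 6 tumours. Markers of stromal cells moved with them, since fibroblast markers rose (median 1.29, 18 of 19 higher), with a median of 0.76 without N 1, with Col1a2 at 265 ± 106 (SD, n = 6) against 78.0 ± 40.6 CPM (SD, n = 5). Only 12 of the 19 fibroblast genes lay outside the matrix and mesenchymal lists, so a part of this rise is the same genes. Macrophage markers rose as well (median 1.03, 17 of 19), with the lysosomal protease gene Lgmn at 264 ± 61.6 (SD, n = 6) against 131 ± 49.2 CPM (SD, n = 5).

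Targets of p53 fell in the same tumours, with 25 of 35 lower (median -0.29; adjusted p = 0.745 with an estimated correlation). That p was 0.649 for glycolysis and 0.775 for the other lists that fell. The death receptor gene Tnfrsf10b was at 22.2 ± 7.3 (SD, n = 6) against 41.4 ± 13.5 CPM (SD, n = 5), and Zmat3, an RNA-binding mediator of p53, at 44.3 ± 11.3 against 98.1 ± 36.3 CPM (SD, n = 6 and 5). Ephx1, an epoxide hydrolase gene (-2.24 ± 0.59 SE), and Psrc1 (-3.06 ± 0.86 SE) were also lower. Glycolysis genes fell with 16 of 21 lower (median -0.38), and Pfkl, a phosphofructokinase subunit, was at 132 ± 22.8 (SD, n = 6) against 262 ± 62.5 CPM (SD, n = 5), lower in 6 of 6. Output genes of MAPK signalling fell (median -0.44, 17 of 20; the receptor gene Epha2 -0.96 ± 0.23 SE), a call lost without N 1 (-0.17). Unfolded protein response genes fell (median -0.35, 23 of 26; Ddit3 -0.87 ± 0.26 SE), a call lost without SL/L 2 (-0.15). Fatty acid synthesis genes fell (median -0.40, 12 of 15; Acacb -0.95 ± 0.28 SE), a call lost without SL/+ 2 (-0.34), P 1 (-0.36), SL/L 2 (-0.33), N 1 (-0.22) and PSL/L 1 (-0.38). MHC class II genes fell (median -0.55, 9 of 11; Ciita -0.89 ± 0.4 SE), a call lost without PSL/+ 1 (-0.21) and with a median of -0.89 without PSL/L 2.

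Further lists rose with the p53 label, with an adjusted p with an estimated correlation of 0.305 for neuroendocrine markers, 0.789 for interferon response, 0.809 for T cells and 0.775 for the rest. Neuroendocrine markers were among them (median 1.05, 12 of 14; Uchl1 2.05 ± 0.51 SE), with a median of 1.91 without SL/L 1 and 0.57 without N 1. Cytosolic ribosome genes rose (median 0.26, 51 of 53; Rps7 0.8 ± 0.23 SE), with a median of 0.15 without SL/L 1 and 0.40 without SL/L 2. Replication-dependent histone genes rose (median 0.46, 17 of 18; Hist1h2ac 1.46 ± 0.38 SE), a call lost without PSL/+ 1 (0.39). G2/M genes rose (median 0.35, 39 of 45), a call lost without SL/+ 2 (0.23), SL/L 2 (0.18) and N 1 (0.16) and with a median of 0.61 without SL/L 1, although Kif23, the member with the smallest p, was at -1.13 ± 0.28 (SE). Interferon response genes rose slightly (median 0.14, 24 of 39; Xaf1 1.46 ± 0.26 SE), a call lost without SL/+ 1 (0.07), SL/L 2 (0.07), PSL/+ 1 (0.27), N 1 (-0.02), P 2 (0.12) and PSL/L 2 (0.10) and with a median of 0.67 without SL/L 1, 0.35 without SL/+ 2 and 0.37 without PSL/L 1. Alveolar macrophage markers rose (median 0.96, 15 of 16; the cholesterol transporter gene Abcg1 1.19 ± 0.37 SE), a call lost without N 1 (0.72) and with a median of 1.49 without SL/L 2. Endothelial markers rose (median 0.41, 17 of 20; Lyve1 1.12 ± 0.43 SE), a call lost without SL/L 1 (0.28), N 1 (0.14) and PSL/L 1 (0.27) and with a median of 0.77 without PSL/+ 1. Smooth muscle markers rose (median 0.87, 12 of 14; Des 1.29 ± 0.49 SE), a call lost without SL/L 1 (0.63), N 1 (0.38) and PSL/L 1 (0.73). Cardiac muscle markers rose (median 1.15, 13 of 14; Myh6 3.39 ± 1.35 SE), a call lost without N 1 (0.52) and PSL/L 2 (0.77) and with a median of 0.64 without P 1. Adipocyte markers rose (median 1.17, 9 of 11; Lpl 1.01 ± 0.37 SE), a call lost without SL/L 1 (0.95), SL/L 2 (1.30), N 1 (0.28) and PSL/L 2 (0.98). Natural killer cell markers rose (median 1.23, 8 of 8; Klrb1c 2.66 ± 0.87 SE), a call lost without N 1 (0.41) and P 2 (1.03). T cell markers rose (median 0.996, 16 of 18; Lat 1.93 ± 1.48 SE), a call lost without SL/L 1 (0.83), SL/+ 1 (0.95), N 1 (-0.03), P 2 (0.34) and PSL/L 2 (0.71) and with a median of 1.77 without SL/L 2, 1.83 without PSL/+ 1 and 1.57 without PSL/L 1.

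With the p53 label edgeR found 0 genes at FDR under 0.05, 2084 at an unadjusted p under 0.05 (1022 higher, 1062 lower; chance gives 818), DESeq2 702 (346 higher, 356 lower) and limma-voom 0. Without SL/L 2 edgeR called 36 genes (14 higher, 22 lower), without SL/+ 2 it called 3, without SL/L 1 it called 2, and without both SL/L 2 and P 2 it called 10. The genes with the smallest p included Mmd at 26.9 ± 9.17 (SD, n = 6) against 10.6 ± 2.27 CPM (SD, n = 5), Bnipl (-1.56 ± 0.2 SE), the proprotein convertase gene Pcsk6 (-1.99 ± 0.26 SE) and Il4i1 (-2.19 ± 0.3 SE), each with edgeR adjusted p = 0.0763. Acot1, an acyl-CoA thioesterase gene, was at 35.3 ± 19.3 against 8.09 ± 2.48 CPM (SD, n = 6 and 5; edgeR adjusted p = 0.0772). Prkar2b, a protein kinase A subunit gene, was at 22.4 ± 6.95 against 7.16 ± 2.63 CPM (SD, n = 6 and 5; edgeR adjusted p = 0.0887). By camera 23 of 54 lists passed, led by matrix (adjusted p = 3.28e-11), mesenchymal (5.96e-09) and junction genes (2.16e-08), with p53 targets at 0.00145. None held with an estimated correlation, the adjusted p with an estimated correlation being 0.305 for mesenchymal and neuroendocrine genes and between 0.649 and 0.809 for the other lists. Adjusted over the list alone, 18 matrix genes (17 higher, 1 lower), 11 mesenchymal, 6 junction, 4 glycolysis, 4 p53 target, 2 neuroendocrine, 2 MAPK, 1 macrophage and 1 interferon gene passed. fry, which tests whether the genes of a list move, on balance, one way, called 2 lists here, mesenchymal and neuroendocrine (both adjusted p = 0.0229), and 0 in the other 5 comparisons between groups.

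**Figure D3:**
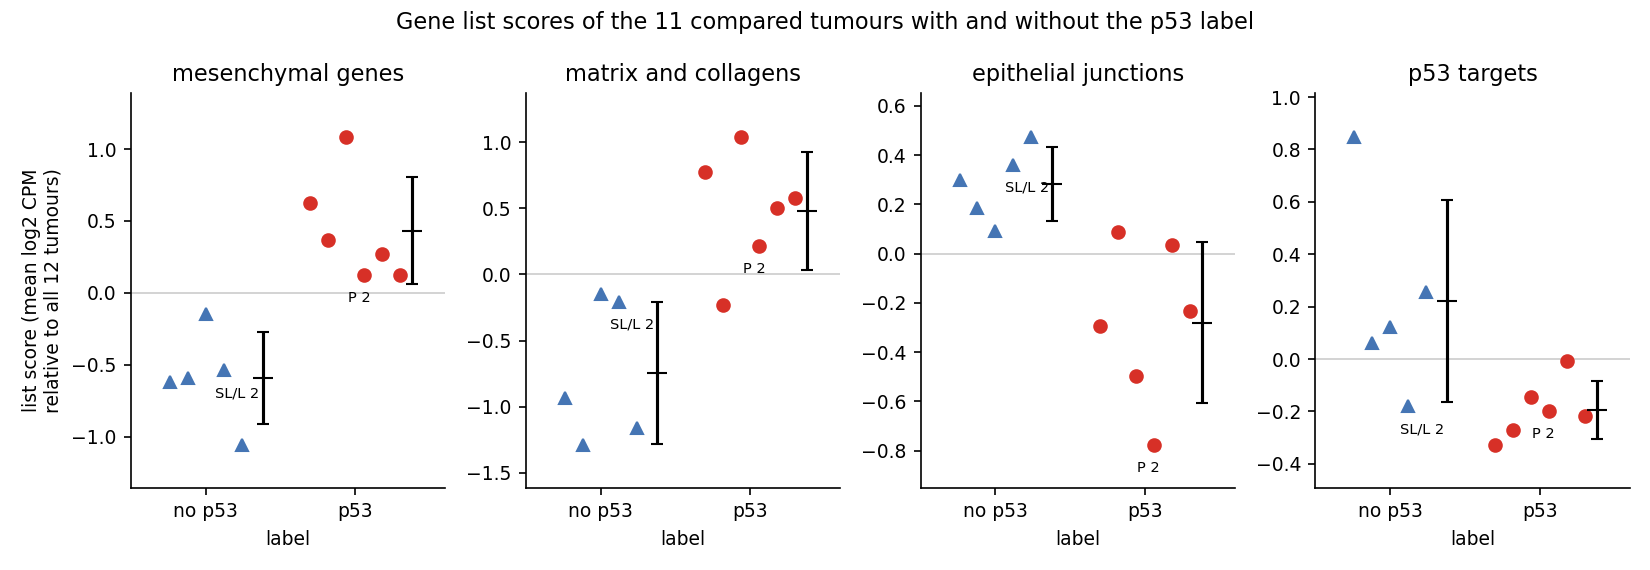
Mean log2 CPM of list members relative to the mean of all 12 tumours in tumours with the p53 label (circles) and without it (triangles), 1 point per tumour, with bars for the mean ± SD; SL/L 2 and P 2 mark the libraries named so in the text. The group means differ by 1.03 for mesenchymal genes, where all 6 tumours with the p53 label lie above the other 5, and by -0.56 for junction genes.

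A pair of direct comparisons between genotypes completed the design. The first asked what went with the Smarca4L/L label among tumours with the p53 label, with 2 tumours against 3 with p53 alone (adjusted p = 0.724 with an estimated correlation for each called list). Oxidative phosphorylation genes rose (median 0.42, 74 of 76), with a median of 0.66 without PSL/L 1 and 0.17 without PSL/L 2, and Cox8a, of complex IV, was at 129 ± 31.5 (SD, n = 2) against 68.2 ± 9.41 CPM (SD, n = 3). Cytosolic ribosome genes rose (median 0.44, 53 of 53; Rpl26 1.1 ± 0.28 SE). Mitochondrial ribosome genes rose (median 0.30, 40 of 46; Mrpl3 0.56 ± 0.2 SE), with a median of 0.19 without PSL/L 2. Tricarboxylic acid cycle genes rose (median 0.17, 18 of 23; Idh3a 0.85 ± 0.26 SE), a call lost without PSL/L 2 (0.09). Cholesterol synthesis genes rose (median 0.70, 21 of 21; Insig1 1.18 ± 0.34 SE), a call lost without PSL/L 2 (0.21) and with a median of 1.14 without PSL/L 1 and 1.14 without P 3. G2/M genes fell (median -0.56, 40 of 45; Mki67 -1.08 ± 0.39 SE), with a median of -0.94 without PSL/L 2. DNA replication genes fell (median -0.53, 35 of 43; Mcm5 -1.26 ± 0.34 SE), with a median of -0.35 without P 1. MHC class II genes fell (median -0.66, 11 of 11), a call lost without PSL/L 1 (-0.28) and with a median of -1.27 without PSL/L 2, and Ciita was at 24.0 ± 0.523 (SD, n = 2) against 81.0 ± 23.4 CPM (SD, n = 3). Smarca4 itself was at 69.0 ± 24.3 (SD, n = 2) against 180 ± 24.7 CPM (SD, n = 3; edgeR adjusted p = 0.594).

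Markers of other cells moved with these groups (adjusted p = 0.724 with an estimated correlation for each list). T cell markers fell (median -3.88, 18 of 18; Foxp3 -2.36 ± 0.93 SE), with a median of -0.71 without P 2. B or plasma cell markers fell (median -4.79, 14 of 14; Cr2 -6.44 ± 2.4 SE), a call lost without P 2 (-0.14). Natural killer cell markers fell (median -1.93, 11 of 11; the perforin gene Prf1 -3.35 ± 1.31 SE), a call lost without PSL/L 1 (-1.43) and P 2 (-0.62) and with a median of -3.20 without PSL/L 2. Dendritic cell markers fell (median -1.53, 11 of 13; Siglech -3.55 ± 1.5 SE), a call lost without PSL/L 2 (-1.16) and with a median of -0.70 without P 2. Neutrophil markers fell (median -1.05, 14 of 17; Cxcr2 -1.05 ± 0.33 SE), a call lost without SL/L 1 (-1.06), SL/L 2 (-1.05), PSL/L 1 (-0.83) and P 2 (-0.39) and with a median of -1.91 without PSL/L 2. Chemokine genes fell (median -0.78, 25 of 31; Csf1 -1.72 ± 0.64 SE), a call lost without PSL/L 1 (-0.41) and with a median of -1.65 without PSL/L 2. Interferon response genes fell (median -0.28, 34 of 39; Stat2 -0.76 ± 0.33 SE), a call lost without PSL/L 1 (0.11) and P 2 (-0.19) and with a median of -0.45 without P 1 and -1.05 without PSL/L 2. Endothelial markers fell (median -0.42, 15 of 20), a call lost without PSL/L 2 (-0.28) and P 3 (-0.33) and with a median of -0.72 without PSL/L 1, and Egfl7 was at 27.2 ± 0.18 (SD, n = 2) against 54.4 ± 1.13 CPM (SD, n = 3).

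Lists of muscle, fat and liver genes fell as well (adjusted p = 0.724 with an estimated correlation for each list). Cardiac muscle markers fell (median -1.32, 14 of 16; Ttn, the sarcomere gene titin, -3.03 ± 0.66 SE), a call lost without P 1 (-0.70) and PSL/L 1 (-0.71) and with a median of -3.34 without PSL/L 2. Skeletal muscle markers, which also hold Ttn, fell (median -0.77, 13 of 15), a call lost without SL/L 1 (-0.77), P 1 (-0.36), SL/L 2 (-0.77) and PSL/L 1 (-0.76) and with a median of -1.55 without PSL/L 2. Adipocyte markers fell (median -1.47, 13 of 13; the brown fat uncoupling gene Ucp1 -7.28 ± 3.27 SE), a call lost without SL/L 1 (-1.48), SL/+ 1 (-1.47), SL/+ 2 (-1.47), SL/L 2 (-1.48), PSL/L 1 (-1.91) and P 2 (0.36) and with a median of -3.04 without PSL/L 2. Hepatocyte genes fell (median -1.93, 12 of 17; Serpina1a -2.03 ± 0.77 SE), a call lost without SL/L 1 (-1.93), SL/+ 1 (-1.93), SL/+ 2 (-1.93), P 1 (-1.41), SL/L 2 (-1.93), PSL/+ 1 (-1.90), PSL/L 1 (-1.60) and P 2 (-1.58). Y-linked genes fell (median -8.02, 4 of 4; Ddx3y -7.99 ± 3.04 SE), a call lost without SL/L 1 (-8.03), P 1 (-7.68), SL/L 2 (-8.02), PSL/L 1 (-7.25), PSL/L 2 (-10.99) and P 3 (-7.60). Ddx3y was at 0.282 ± 0.277 (SD, n = 2) against 69.2 ± 59.8 CPM (SD, n = 3), so the arms differed in the sex chromosome content of their tumours.

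In this direct comparison edgeR found 0 of 17108 genes at FDR under 0.05, 1391 at an unadjusted p under 0.05 (713 higher, 678 lower; chance gives 855), DESeq2 124 and limma-voom 0. Il4i1 was at 2.12 ± 0.43 (SD, n = 2) against 18.4 ± 5.39 CPM (SD, n = 3), Noxo1 at -2.29 ± 0.46 (SE) and Zc3h7a at -0.99 ± 0.2 (SE). Higher were the small Cajal body RNA Scarna6 (1.31 ± 0.23 SE), the sulfotransferase gene Chst13 (6.26 ± 1.12 SE) and Crispld1 (6.39 ± 1.27 SE). None of these 6 passed (edgeR adjusted p = 0.594). By camera 21 of 54 lists passed, oxidative phosphorylation with adjusted p = 4.44e-12 and cytosolic ribosome with 4e-11, and none held with an estimated correlation (adjusted p = 0.724 with an estimated correlation for each). Adjusted over the list alone, 4 Y-linked genes and 1 gene each of the MHC class II, cardiac and skeletal muscle lists passed, and 0 members of the other 17 lists.

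The second direct comparison set the 2 tumours labelled Smarca4L/L alone against the 2 labelled Smarca4L/+ alone (adjusted p = 0.956 with an estimated correlation for oxidative phosphorylation and 0.951 for the other called lists). Both Smarca4L/L libraries here are doubted. SL/L 2 held 3.38 CPM of Trp53 against 33.8 CPM in SL/+ 1 and 22.2 CPM in SL/+ 2, and SL/L 1 held both Xist and Y-linked transcripts. A difference in p53 status is thus not ruled out beside the Smarca4 label. Cholesterol synthesis genes rose with 21 of 21 higher (median 0.96), and Insig1 was at 136 ± 15.3 against 52.9 ± 11.3 CPM (SD, n = 2 each). Replication-dependent histone genes, a list fixed as a technical sign, rose with 18 of 18 higher (median 0.80), such as Hist1h4a at 28.1 ± 0.13 against 13.7 ± 0.614 CPM (SD, n = 2 each). G2/M genes rose (median 0.50, 40 of 45; the securin gene Pttg1 3.18 ± 0.73 SE), a call lost without SL/L 1 (-0.13) and SL/+ 2 (0.31) and with a median of 0.94 without SL/+ 1 and 0.97 without SL/L 2. Interferon response genes rose (median 0.84, 34 of 39; Xaf1 1.18 ± 0.35 SE), a call lost without SL/L 1 (-0.08) and SL/+ 1 (0.37) and with a median of 1.39 without SL/+ 2. MAPK output genes fell (median -0.51, 15 of 20), a call lost without SL/L 1 (-0.38) and with a median of -0.29 without SL/+ 1 and -0.77 without SL/L 2, and the immediate early gene Egr1 was at 9.68 ± 3.34 against 38.04 ± 8.23 CPM (SD, n = 2 each). Unfolded protein response genes rose (median 0.34, 22 of 26; Sdf2l1 1.38 ± 0.4 SE), a call lost without SL/+ 2 (0.36) and SL/L 2 (-0.27) and with a median of 0.77 without SL/L 1. Oxidative phosphorylation genes rose (median 0.16, 58 of 76; Cox8a 0.55 ± 0.27 SE), a call lost without SL/+ 2 (0.15) and SL/L 2 (-0.08) and with a median of 0.35 without SL/L 1. Fatty acid oxidation genes fell (median -0.22, 16 of 21; Hadh -0.59 ± 0.36 SE), a call lost without SL/L 1 (-0.19), SL/+ 1 (-0.04), P 1 (-0.22), PSL/L 1 (-0.22), P 2 (-0.22), PSL/L 2 (-0.22) and P 3 (-0.22).

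Epithelial markers differed between these tumours (adjusted p = 0.951 with an estimated correlation for each list). Basal and squamous markers rose (median 5.41, 14 of 14; the keratin gene Krt6a 8.28 ± 2.2 SE), a call lost without SL/L 1 (-0.13). Club cell markers rose (median 2.52, 11 of 11; Hp 1.56 ± 0.57 SE), a call lost without SL/L 1 (-2.34) and SL/+ 1 (1.86) and with a median of 4.68 without SL/+ 2. Mesothelial markers rose (median 2.51, 9 of 10; Msln 2.32 ± 0.79 SE), a call lost without SL/+ 1 (2.26) and SL/L 2 (2.14). Alveolar type 2 markers fell (median -0.41, 12 of 16; the surfactant gene Sftpd -0.86 ± 0.48 SE), a call lost without SL/L 1 (0.08) and SL/+ 2 (-0.13) and with a median of -0.63 without SL/+ 1 and -1.49 without SL/L 2. Endothelial markers fell (median -0.25, 16 of 20; Egfl7 -0.67 ± 0.28 SE), a call lost without SL/L 1 (0.05) and SL/+ 2 (0.02) and with a median of -0.46 without SL/+ 1 and -0.83 without SL/L 2.

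Between these 2 genotypes edgeR found 0 genes at FDR under 0.05, 630 at an unadjusted p under 0.05 (394 higher, 236 lower; chance gives 855), DESeq2 71 and limma-voom 0, and edgeR called 1 gene without SL/L 1. The genes closest to passing (edgeR adjusted p = 1) included the guanine nucleotide exchange factor gene Vav3 (2.11 ± 0.31 SE), the protease gene Prss27 (3.39 ± 0.69 SE) and the carbonic anhydrase gene Car9 (3.75 ± 0.76 SE). Lower were Rtn4rl1 (-1.84 ± 0.31 SE), Adam22 (-1.68 ± 0.31 SE) and the glypican gene Gpc1 at 28.2 ± 9.79 against 143 ± 19.4 CPM (SD, n = 2 each). By camera 13 of 54 lists passed, cholesterol synthesis with adjusted p = 6.04e-09, and none held with an estimated correlation (adjusted p = 0.956 with an estimated correlation for oxidative phosphorylation and 0.951 for the other lists). Adjusted over the list alone, 2 squamous genes and 1 MAPK gene passed, and 0 members of the other 11 lists.

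Cell type scores showed how single tumours stood apart from the rest. SL/L 1 had the highest squamous score (4.02 log2 units above the mean of the tumours), a club cell score of 3.54 and 7562 CPM of the secretoglobin gene Scgb1a1. It also held both Xist (34.9 CPM) and the Y-linked gene Ddx3y (91.8 CPM), so RNA of more than 1 animal is not ruled out for any value of this library. Given its squamous and club cell scores, RNA of adjacent tissue is not ruled out either. P 2 had T, B and natural killer cell scores of 4.83, 5.61 and 3.14, and an adipocyte score of 3.93 with 41.9 CPM of Ucp1. PSL/+ 1 had a hepatocyte score of 2.86 and a gastric score of 1.56. The gastric score of P 1 was 1.54 and its cardiac muscle score 2.39.

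**Figure D4:**
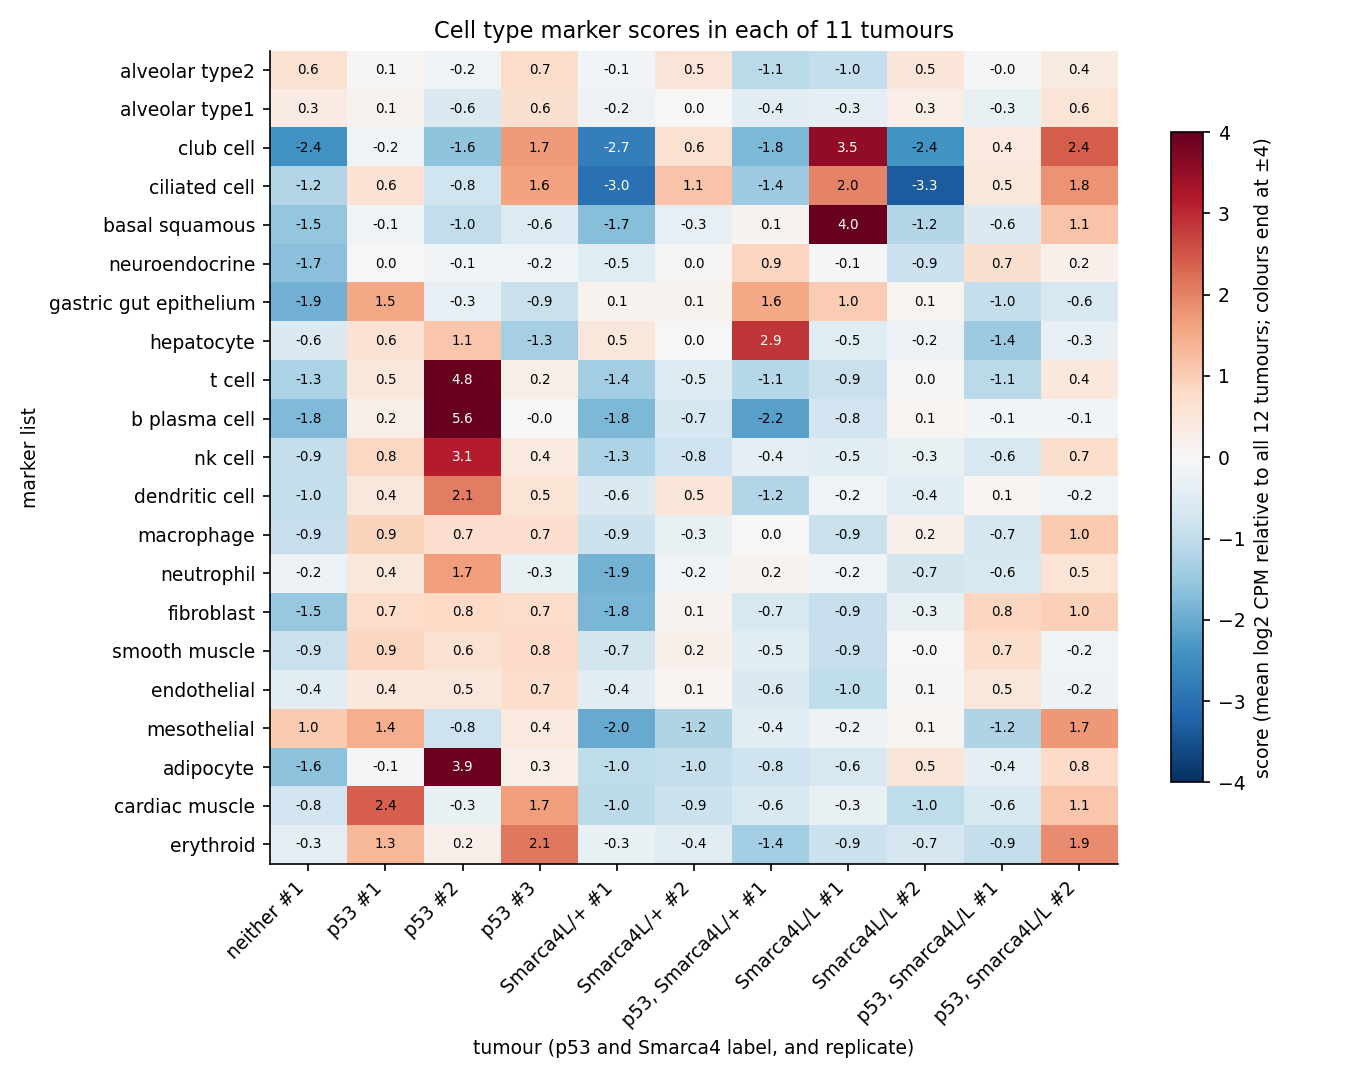
Heat map of cell type marker scores (mean log2 CPM of markers relative to the mean of all 12 tumours) with tumours on one axis and cell types on the other, and colours ending at plus and minus 4. The highest squamous score (4.02) is in SL/L 1, and the highest T cell score (4.83) and B or plasma cell score (5.61) are in P 2.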

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

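Of the tests of explanations in this part, the counts of other splits, the swap, lymphocyte, wrong label, left-out library and tumour cell share tests were chosen only after the result was seen, while the transcript length and fibroblast covariate tests were not.

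In 8 of 90 tests of 1 measure in 1 group of 4 to 6 tumours, 1 tumour lay far from the rest by Dixon's ratio. Chance alone flags about 1 in 20 tests (4.5 expected), and these tests shared a few groups and their tumours, so they are not independent. Among Smarca4L/L tumours the cytosolic ribosome score of SL/L 1 was -0.41, with the next at 0.26. Among tumours with no Smarca4 label the neuroendocrine score of N 1 was -1.66, with the next at -0.16. Among tumours with the p53 label, P 2 had an adipocyte score of 3.93 (next 0.77) and a T cell score of 4.83 (next 0.46). In the same group PSL/L 1 had an alveolar macrophage score of -0.86 (next 0.38) and PSL/+ 1 a fibroblast score of -0.65 (next 0.72). Among tumours with no p53 label, SL/L 2 held 3.38 CPM of Trp53 (next 19.5) and had an unfolded protein response score of 0.91 (next 0.1).

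The Smarca4L/L effect was compared between tumours with and without the p53 label, where the 1 tumour with neither label was assumed to vary like the others. edgeR found 0 genes for this difference (643 at an unadjusted p under 0.05), while camera called 20 lists, none with an estimated correlation (adjusted p = 0.889 with an estimated correlation for each). No difference is established by list, because the effect without the p53 label set SL/L 1 and SL/L 2, both doubted, against 1 tumour (N 1), and no tumour was left out for this contrast. The arms also differed in sex chromosome content. Ddx3y was at 91.8 and 160.9 CPM in SL/L 1 and SL/L 2, against 0.0362 CPM in N 1. In PSL/L 1 and PSL/L 2 it was at 0.0866 and 0.478 CPM. In P 1, P 2 and P 3 it was at 98.9, 0.395 and 108.3 CPM. An effect of sex cannot be told apart from this difference. The median difference (with minus without the p53 label) was positive for MAPK output (1.06), alveolar type 2 markers (0.74), epithelial junctions (0.32), oxidative phosphorylation (0.3) and the mitochondrial ribosome (0.21). It was negative for Y-linked genes (-18.35), B or plasma cells (-6.66), the foregut programme (-6.11), T cells (-4.86), adipocytes (-4.6), natural killer cells (-4.5) and gastric epithelium (-4.34). Smaller negative values were found for dendritic cells (-3.1), skeletal muscle (-2.21), alveolar macrophages (-1.61), cardiac muscle (-1.53), smooth muscle (-1.43), macrophages (-1.27), interferon response (-0.84) and G2/M genes (-0.49). With the p53 label P 2 carried much of the effect on lymphocytes and fat, whose medians without it were -0.14 for B or plasma cells, -0.71 for T cells, -0.62 for natural killer cells and 0.36 for adipocytes.

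Trp53 levels went against the p53 label in SL/L 2 and P 2. Smarca4 levels argue against a swap of these libraries with each other, because each lay at least 3.4 SD from the group it would join. Each SD came from only a few libraries, so a swap is not excluded. RNA of lymphocytes with intact Trp53 may have raised Trp53 in P 2, whose T cell score exceeded the next library with the p53 label by 4.37 and whose B cell score exceeded it by 5.39, while its p53 target score of -0.2 stayed within the range of that group (-0.33 to -0.01). A wrong p53 label on SL/L 2 stays open, since its p53 target score was -0.18 against 0.06 to 0.85 in the other libraries with no p53 label. Loss of p53 function within that tumour would give the same values and was not tested separately.

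Oxidative phosphorylation and cytosolic ribosome genes were higher in Smarca4L/L tumours. Both medians (0.34 and 0.42) lay at percentile 100 of random lists matched on expression and length, whose medians centred on 0.11 and 0.15. This argues against their short transcripts as the whole cause. It does not exclude them, because the random lists held unrelated genes, while the estimated correlations within these lists were 0.54 and 0.66. Lymphocyte RNA in P 2 is excluded as the whole cause for oxidative phosphorylation, whose median was 0.28 without that library. Chance is not excluded, because 5 of the 35 splits of the same tumours gave as strong a call for oxidative phosphorylation (-log10 p of 11.48, highest other split 26.08). An effect that goes with the Smarca4 label, or a shared composition of these tumours, may each remain.

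Mesenchymal and matrix genes were higher with the p53 label. A lower share of tumour cells was predicted to raise all other cell types alike. Fibroblast scores rose more than smooth muscle scores (difference 0.59, larger exact p = 0.0455) and endothelial scores (0.88, exact p = 0.0195). They did not rise detectably more than macrophage scores (0.46, exact p = 0.305). A lower share of tumour cells is not excluded by this, because the mix of other cell types can also differ between tumours. With a fibroblast score from 12 genes as covariate the mesenchymal median went from 1.19 to 0.85 and the junction median from -0.49 to -0.27. The mesenchymal list then had a camera adjusted p of 2.32e-07 with the preset correlation. Without the covariate its camera adjusted p with an estimated correlation was 0.305. More fibroblast RNA is not excluded as the whole cause for the mesenchymal genes, because this score may adjust for it only in part. With the same covariate the median of the 23 matrix genes outside the fibroblast list went from 1.24 to 0.71 (camera adjusted p from 1.59e-08 to 0.00182). Fibroblast RNA may thus account for at least a part of the matrix change. Chance is not excluded for the mesenchymal call, which was singled out from 54 lists, because in 85 of 100 splits drawn from 462 some list was called as strongly (-log10 p of 9.66, highest other 30.41). The mesenchymal list itself reached at most 7.21 in the other splits. A change of cell state that goes with the p53 label may remain as a hypothesis, found and tested on the same data.

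Other splits of the tumours were counted for each comparison of at least 3 against 3, the real split included, with 100 drawn from 462 for the p53 label. The edgeR count was 0 in each comparison, which all 35, 35, 35 and 100 splits reach by construction (highest other 2, 0, 0 and 9), so it tests nothing. For Smarca4L/L against no Smarca4 label chance is not excluded for the 1735 genes at unadjusted p (2 of 35 splits, highest other 1890) or the 14 lists (35 of 35, highest other 30). No other split reached the 343 genes by DESeq2 (1 of 35, highest other 320), by a narrow margin and at the smallest share that 35 splits allow. Several counts were compared in this way without adjustment, and DESeq2 splits were run only here. For this count, too, chance is therefore not excluded. For Smarca4L/+ against no Smarca4 label it is not excluded for the 1125 genes (5 of 35, highest other 1924) or the 29 lists (3 of 35, highest other 30). For Smarca4L/L against Smarca4L/+ it is not excluded for the 785 genes (26 of 35, highest other 2395) or the 14 lists (25 of 35, highest other 24). With the p53 label chance is not excluded for the 23 lists (33 of 100, highest other 30). No other split that was run reached the 2084 genes at unadjusted p (1 of 100, highest other 2052). The margin was narrow and 362 splits were not run, so chance is not excluded for these genes either. The 2395 genes at unadjusted p were the most of any split of Smarca4L/L against Smarca4L/+, where the median of the other splits was 1033. What set that split apart was not tested.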

How the results depend on the processing

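The fits without the 2 libraries whose Trp53 level went against their label, and without these and SL/L 1, were chosen only after the result was seen. Across 4413 values of named genes under the alternatives, 6 took the other direction, and 97 passed the threshold, 85 of them by DESeq2. Of 2060 list medians, 38 took the other direction. Where values changed, the cause was not tested. No paired analysis was possible because the labels pair no tumours. With at least 27258872 counts per tumour, depth limits the rarest transcripts, for which a count of 0 allows up to 3 counts per library.

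DESeq2 called 343 genes for Smarca4L/L and 65 for Smarca4L/+ against no Smarca4 label, 67 for Smarca4L/L against Smarca4L/+, 702 for the p53 label, 124 for p53 with Smarca4L/L against p53 alone and 71 for Smarca4L/L against Smarca4L/+ with no p53 label. The other settings with all tumours gave 0 by edgeR or limma-voom. With the p53 label edgeR called 10 genes without the 2 discordant libraries and 1 without the 3 doubted libraries, and 0 to 36 when 1 tumour was left out. Leaving out 1 tumour gave 0 to 1 genes for Smarca4L/L against Smarca4L/+ with no p53 label. An estimated correlation left 0 lists in each of the 6 comparisons, and fry called 0 except for 2 with the p53 label. Its mixed test, in which genes of a list may move both ways, called 1 list for Smarca4L/L against no Smarca4 label (tricarboxylic acid cycle, adjusted p = 0.0077) and 8 with the p53 label. With a leukocyte score as covariate, camera called 17 lists for Smarca4L/+ against no Smarca4 label in place of 29, and 10 for p53 with Smarca4L/L against p53 alone in place of 21. The number of called lists without 1 tumour ran from 14 to 23 (Smarca4L/L), 12 to 34 (Smarca4L/+), 8 to 18 (Smarca4L/L against Smarca4L/+), 14 to 28 (p53) and 10 to 20 (Smarca4L/L against Smarca4L/+ with no p53 label). The Smarca4 fold change of Smarca4L/L tumours ran from -1.52 to -1.14.

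Library size scaling in place of TMM moved the median of all genes to 0.15 for the p53 label and to -0.34 for the difference of the Smarca4L/L effect (-0.18 with upper quartile scaling). The share of genes at unadjusted p that were higher then went from 49 to 76.6% for the p53 label (56.2% with upper quartile), from 51.3 to 34.2% for p53 with Smarca4L/L against p53 alone (43.4%), from 48.5 to 37% for Smarca4L/L against Smarca4L/+, from 54 to 65% for Smarca4L/+ and from 49.1 to 19.1% for the difference. Among called lists 1 changed sign, the mitochondrial ribosome in the difference, from 0.21 to -0.05.

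Some directions reversed. With the Y-linked score as covariate the T cell median was -0.26 for the p53 label and the Y-linked median 0.09 for p53 with Smarca4L/L against p53 alone. With the leukocyte score the dendritic cell median was 0.07 for Smarca4L/L, and with the p53 label the values were -0.76 for Lat, -0.29 for adipocytes, -0.08 for interferon response, -0.06 for natural killer cells and -0.85 for T cells. For p53 with Smarca4L/L against p53 alone this covariate gave 0.25 for adipocytes, 0.03 for B cells and 0.05 for neutrophils. Without the 2 discordant libraries adipocyte medians were 0.49 for Smarca4L/+ and 0.28 for p53 with Smarca4L/L against p53 alone. Without the 3 doubted libraries these medians were 0.07 and 0.26. Trp53 was at 0.51 for Smarca4L/+ with no p53 term, and Smarca4 at 0.08 for the p53 label with no Smarca4 term.

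Leaving out 1 tumour at a time gave these ranges for values that reversed. For Smarca4L/+ against no Smarca4 label the ranges were -1.01 to 0.09 for Trp53, -2.93 to 0.4 for adipocytes, -0.68 to 0.1 for endothelium, -0.09 to 1.76 for the foregut programme, -0.39 to 1.3 for gastric epithelium and -0.13 to 2.69 for hepatocytes. For Smarca4L/L against Smarca4L/+ they were -0.82 to 3.39 for ciliated cells, -0.16 to 4.06 for club cells, -0.08 to 0.8 for matrix genes and -0.19 to 1.09 for fibroblasts. For the p53 label they were -0.02 to 0.67 for interferon response and -0.03 to 1.83 for T cells. For p53 with Smarca4L/L against p53 alone they were -3.04 to 0.36 for adipocytes and -1.05 to 0.11 for interferon response. For Smarca4L/L against Smarca4L/+ with no p53 label they were -0.79 to 0.05 for Smarca4 and -3.07 to 0.01 for Trp53. The list medians there ran from -1.49 to 0.08 for alveolar type 2 cells, -0.13 to 7.07 for squamous markers, -0.13 to 0.97 for G2/M genes, -2.34 to 4.68 for club cells, -0.83 to 0.05 for endothelium, -0.08 to 1.39 for interferon response, -0.08 to 0.35 for oxidative phosphorylation and -0.27 to 0.77 for the unfolded protein response.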

Other observations

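The tests in this part were chosen only after the result was seen. Single tumours carried transcripts of other tissues. P 2 held 41.9 CPM of Ucp1, the uncoupling protein of brown fat, where the next tumour had 2.04 CPM. The same library held 43.5 CPM of the complement receptor gene Cr2. PSL/+ 1 held 216 CPM of the albumin gene Alb and 1680 CPM of Apob, while the Smarca4L/L tumours held 6.16 to 7.62 CPM of Apob.

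SL/L 1 held transcripts of airway and squamous epithelium together, with scores of 3.54 for club cells, 1.97 for ciliated cells and 4.02 for squamous markers. It held 34.9 CPM of Xist, the RNA that silences an X chromosome, together with 91.8 CPM of the Y-linked gene Ddx3y. Whether it held RNA of more than 1 animal or of adjacent tissue was not tested. The cell type list scores with the p53 label were also compared by exact two-sided permutation tests over 462 arrangements. The score differences were 1.03 for mesenchymal genes (exact p = 0.00216, the smallest possible), 1.23 for matrix genes, 1.44 for fibroblasts and -0.56 for junction genes (exact p = 0.00866 for each of the last 3). They were 0.86 for smooth muscle (exact p = 0.0346), 0.99 for macrophages (exact p = 0.0238) and 0.56 for endothelium (exact p = 0.0823). Alveolar type 2 markers differed by -0.13 (exact p = 0.736).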
